A study of Mus musculus with 2 samples.

How the data were processed

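Olfactory epithelium of 1 OR1A1 transgenic and 1 wild-type mouse was minced, dissociated with enzymes that included collagenase and DNase I, strained and loaded for 10x Genomics 3′ single-cell RNA-seq with UMIs, per the labels' protocols. The deposited values are raw UMI counts per gene and barcode, given by the authors without filtering to cells: the files list 2037787 transgenic and 1577106 wild-type barcodes, of which 1484206 and 1171736 hold a UMI. Cell Ranger 6.1.1 and the genome build GRCm39 (mm39) are named in the submitters' processing notes, while the matrix headers name Cell Ranger 4. The feature list held 32534 features, 2 of which the authors had added: 1A1_tg, taken here as the transgene, and 10G4, whose sequence is not given in the sources used here. The sequence behind 1A1_tg is not given there either, so it is open which part of the construct its counts come from. The 3′ chemistry reads the ends of transcripts, and reads of near-identical ORs or of a pseudogene and its parent cannot be told apart by the counts.

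Each library was processed on its own up to the calling of cells. A barcode was kept with at least the larger of 1000 UMIs and 10% of the 99th percentile of the 5000 barcodes with most UMIs, which came to 5827.5 UMIs in the transgenic and 5317.7 in the wild-type library, with at least 500 genes and at most 10% mitochondrial UMIs. These steps left 2557, 2494 and 1749 transgenic and 1675, 1638 and 1119 wild-type barcodes. Scrublet, run in scanpy with an expected rate of 0.8% per 1000 cells, marked 4 and 2 cells (0.229% and 0.179%, against expected rates of 1.4% and 0.9%), which were removed. Because so few were marked, an alternative removed the 5% of cells with the highest scores in each library. The kept cells had 8099 to 26654 UMIs (10th to 90th percentile) in the transgenic and 7144 to 29437 in the wild-type library, and median mitochondrial shares of 5.42% and 5.18%. Barcodes under 100 UMIs stood for free RNA, of which 37.4% and 51.3% was mitochondrial.

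Both libraries were clustered together without integration (scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9): totals were scaled to 10000, 2000 variable genes and 30 principal components were used with 15 neighbours, and Leiden clustering at resolution 1 gave 27 clusters. OR, vomeronasal, trace amine, mitochondrial, ribosomal, immunoglobulin, Xist and transgene features were left out of clustering, so that OR and transgene levels could be compared between clusters. Clusters were named from 128 markers of 21 classes fixed with the design. A name needed a mean log2 excess of 1 over the other cells (5 CPM added) and at least 3 markers at 2-fold. A cluster short of this stayed unnamed, as did clusters led by 2 or more genes from a short list set after the data had been seen (secretory genes such as Bpifa1, Reg3g and Dcpp1, and myeloid genes such as Mpo and Ctsg). The 4 unnamed clusters held 5.67% of transgenic (4.63 to 6.86%) and 11.7% of wild-type cells (9.90 to 13.8%). The classes not described in the report took 2.52% and 1.16% (ionocyte-type microvillar-like), 2.29% and 2.06% (tuft-type microvillar-like), 1.15% and 0.716% (Bowman's gland-like), 0.745% and 0.358% (olfactory ensheathing glia-like) and 0.401% and 1.25% (T or NK cell-like) of transgenic and wild-type cells.

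ORs were the 1104 genes with Olfr symbols, with 34 pseudogenes left out. An OR was counted in a cell at 3 or more UMIs and the transgene at 1 or more, with the share at 3 or more beside it. Shares carry exact binomial (Clopper-Pearson) 95% intervals and a share of 0 the limit that 3 counts give. To compare depths, each cell was thinned to 7900 UMIs and shallower cells were left out. The number of leading ORs was compared by 100 random draws of equal numbers of cells. The design assigned class I by newer OR symbols (Or51 to Or56), which the files do not use. Class was instead taken from receptor family numbers among the gene synonyms of a RefSeq table of GRCm38, with families up to 42 as class I, for 1078 ORs of which 122 were class I. This rule was corrected after its values had been seen, by ignoring family 0 and leaving out ORs with families of both classes. From that table only names and neighbours within 200 kb were used, and no coordinate.

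Gene levels were sums of UMIs over the cells of a class, as CPM of all UMIs of the class. The log2 ratio of transgenic over wild type had 1 UMI added to each sum and a conditional binomial interval. A gene was measured with at least 20 CPM and 50 UMIs in 1 library. With 1 library per group no significance was computed. The genes named are the 10 in mature and the 5 in immature cells with the largest ratio in each direction, the 5 ORs leading most mature cells per library, ORs that differed most in share among those leading 10 or more cells in all (1 OR qualified), the 2 added features, Olfr160, Mapt, Omp and Gap43, and the members of 10 fixed lists with the largest ratios. A fold against 0 UMIs is given as a lower bound against 3 UMIs over the class, and none is given where neither library held more than 3. A list median is given with its percentile among 10000 random lists of equal size, matched in 20 bins of mean expression, for lists of at least 3 measured genes. Members past 1.5-fold were counted. Some genes, such as Kirrel2, Nrp2, Plxna1 and Robo2, stood in more than 1 list, so list values are not independent. Ddit3, a member of the OR feedback list, was missed when genes were matched to the lists, so no list value takes it in. The cell filters, markers, lists, rule for named genes and most alternative settings were set before the data were examined. Computations ran in python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

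The gene comparison was tested on simulated data. Counts were drawn at the levels of 7363 genes for mature and 4660 genes for immature cells, with 200 genes changed by 2-fold or 4-fold. In both, the median recovered log2 ratio was 1.00 for 2-fold and 2.00 for 4-fold, all changed genes had the right direction, the intervals covered the true ratio for 95.6% and 94.9% of genes, and 0 unchanged genes reached 2-fold. The draws were made at gene levels, so these values speak to counting error only. They do not cover ratios that rest on 1 cell, such as that of Esp22. The simulated immature genes were also fewer than the 6874 measured. Alternatives covered the UMI minimum, doublets, mitochondrial share, clustering resolution, OR and transgene minima, calling ORs above free RNA by a Poisson test, thinning, scaling, the minimum level of a gene, means over cells in place of sums and, chosen after the results had been seen, sums with the clusters of a class weighted by their share of UMIs in the wild-type library.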

Results

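Single-cell RNA-seq (10x Genomics 3′ chemistry, in which each captured transcript carries a unique molecular identifier, UMI) was done on dissociated olfactory epithelium, the tissue of the nose that holds the olfactory sensory neurons (OSNs). The series held 1 library from a female mouse hemizygous for a transgene of OR1A1, a human odorant receptor (OR), and 1 library from a wild-type female. The name of the construct cites Or8a1, the mouse OR gene that the deposited feature list carries under its older symbol Olfr160, together with OR1A1, MAPT and the fluorescent protein mCherry. The animals were 9 and 8 weeks old, and the strain label of the wild-type animal names a cross with another line, 10G4, so the libraries differed in strain background and age as well as in genotype. The transgenic library held 70572741 UMIs in 1484206 barcodes and the wild-type library 55701219 UMIs in 1171736 barcodes. After filtering, 1745 transgenic and 1117 wild-type cells remained, with medians of 14440 and 12983 UMIs and of 4226 and 3916 genes per cell. With 1 library per group no difference could be set against a spread between animals. No test of a difference between genotypes was made, and every comparison between genotypes is a comparison of 2 libraries. Intervals of ratios of medians, in the closing section, came from resampled cells. Each other interval is an exact 95% interval that covers counting error only.

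Mature OSN-like cells, which express Omp and the olfactory signalling genes, made up 40.6% of transgenic cells (38.3 to 43.0%, 709 cells) and 40.7% of wild-type cells (37.8 to 43.7%, 455 cells). The classes before them in the lineage took larger shares of the transgenic library. Immature OSN-like cells (Gap43, Stmn2) were 15.6% of transgenic cells (14.0 to 17.4%, 273 cells) and 5.82% of wild-type cells (4.52 to 7.36%, 65 cells). Immediate neuronal precursor (INP)-like cells (Neurod1) were 3.95% (3.09 to 4.98%, 69 cells) and 1.43% (0.821 to 2.32%, 16 cells), and globose basal cell (GBC)-like cells, the cycling progenitors marked by Top2a, were 3.04% (2.28 to 3.95%, 53 cells) and 0.627% (0.252 to 1.29%, 7 cells). Among the other epithelial cells, sustentacular-like cells were 4.76% and 1.88% and horizontal basal cell-like cells 3.95% and 1.97%. Several classes of blood and vessel cells went the other way. Neutrophil-like cells were 0.458% of the transgenic library and 7.07% of the wild-type library, endothelial-like cells 4.07% and 7.88% and erythroid-like cells 0.974% and 3.31%. Macrophage- or monocyte-like cells were 4.93% and 8.06%, but their 2 clusters parted: the one led by C1qa was 4.41% (3.50 to 5.48%) of the transgenic and 2.78% (1.89 to 3.92%) of the wild-type library, and the one with Ccl9 and Ccr2 among its leading genes 0.516% (0.236 to 0.977%) and 5.28% (4.04 to 6.76%). Fibroblast-like cells were 4.81% and 3.94%. Dissociation and the UMI minimum can set such shares. The immature share moved with nearly every setting but stayed higher in the transgenic library. The cells named GBC-like changed with the setting. They were 1.34% of transgenic and 4.54% of wild-type cells at a fixed minimum of 500 UMIs, and 0.547% and 3.50% at 2000 UMIs. These minima are lower than the main ones and kept more cells (2314 and 2012 transgenic, against 1745). Fewer transgenic cells nevertheless carried the name, so these shares are not a reversal in the same cells. Which cells the name then covered was not examined. At a clustering resolution of 0.5 no cluster carried that name.

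The series asks where in the lineage the OR transgene is expressed and how it stands to the choice of a single OR gene. The feature added for the transgene was found in a larger share of mature than of immature OSN-like cells of the transgenic library, and in few GBC-like and INP-like cells. At least 1 transgene UMI was found in 7.55% of GBC-like cells (2.09 to 18.2%), 10.1% of INP-like cells (4.18 to 19.8%), 25.3% of immature OSN-like cells (20.2 to 30.9%) and 47.7% of mature OSN-like cells (43.9 to 51.4%). At 3 or more UMIs the shares were 1.89%, 1.45%, 7.69% (4.82 to 11.5%) and 28.2% (24.9 to 31.7%), the first 2 of which stand for 1 cell each. The cells with 3 or more UMIs held a median of 10 transgene UMIs in both the mature (200 cells, at most 32) and the immature class (21 cells, at most 28). Summed over cells, the transgene reached 232 counts per 1000000 UMIs (CPM) in mature and 69.6 CPM in immature OSN-like cells of the transgenic library. No wild-type mature cell (0 of 455, which allows a share of up to 0.659%) or immature cell (0 of 65, up to 4.62%) held a transgene UMI, and all barcodes of the wild-type library held 6 (1 of them in barcodes under 100 UMIs), against 4864 in the transgenic library. Thus the transgene was at least 452-fold higher in transgenic mature cells and at least 25.3-fold higher in immature cells, against a floor of 3 UMIs over the wild-type cells of each class.

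Transgene UMIs in non-neuronal classes gave a background for these shares, and their source was not tested. Free RNA of the transgenic library held 98 transgene UMIs among 2143260. In the transgenic library, fibroblast-like cells (median 10916 UMIs) held at least 1 transgene UMI in 4.76% of cells (1.31 to 11.7%) and macrophage- or monocyte-like cells (median 9292.5 UMIs) in 2.33% (0.283 to 8.15%), and none of these cells held more than 1. Mature OSN-like cells had a median of 14171 UMIs. The GBC-like and INP-like shares at 1 UMI overlapped this background. The single GBC-like and INP-like cells with 3 or more transgene UMIs carried Omp at 732 and 704 CPM, against 28.0 and 51.6 CPM in the remaining cells of their classes. Across all non-neuronal classes 9.04% of cells (6.76 to 11.8%, median 12429 UMIs) had a transgene UMI, and the classes differed. In sustentacular-like cells 21.7% (13.4 to 32.1%) held at least 1 and 8.43% held 3 or more, and these 7 cells had a median of 76061 UMIs and Omp at 1759 CPM, against 442 CPM in the other sustentacular-like cells. Erythroid-like cells held 3 or more in 29.4%, with Omp at 5771 CPM in those cells and 4232 CPM in the others. Mature OSN-like cells of this library had Omp at 4892 CPM, and 9 of the 17 erythroid-like cells held an OR at 3 or more UMIs. These droplets thus held OSN RNA at a neuron's level and are no clean non-neuronal background, though they count in the 9.04%. Endothelial-like cells (median 11783 UMIs) held at least 1 in 14.1% (6.97 to 24.4%), 2 or more in 7.04% and up to 7 UMIs, with Omp at 64.5 CPM in the 2 cells with 3 or more and 36.0 CPM in the others. After thinning each cell to 7900 UMIs the shares with at least 1 transgene UMI were 5.66% in GBC-like, 1.47% in INP-like, 16.3% in immature, 37.9% in mature OSN-like and 5.26% in fibroblast-like cells. A second random thinning gave 3.77% and 5.88% in GBC-like and INP-like cells, so these 2 shares depended on the draw.

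Within the immature class the transgene differed between 3 clusters. In the earliest, led by Tex15, 19.0% of 58 transgenic cells (9.87 to 31.4%) had at least 1 transgene UMI, a share that overlapped those of the endothelial-like and sustentacular-like cells, and none had more than 3. In the Gap43-led cluster 24.2% of 124 cells (17.0 to 32.7%) had at least 1 and 4.03% (1.32 to 9.16%) had 3 or more. In the cluster led by Calb2 the share at 3 or more was 16.5% of 91 cells (9.53 to 25.7%). Set against the endogenous receptors, the transgene was detected in more mature cells (338) than any of the 486 ORs detected there, of which Olfr365 came next with 57 cells. At 1 UMI it was also found in more cells than any OR in each immature cluster, with 11 cells against 8 for Olfr482 in the earliest (355 ORs; 6.46% of non-neuronal cells also held Olfr482), 30 against 19 in the Gap43-led and 28 against 20 in the Calb2-led cluster. The transgene out-counted every endogenous OR, at 3 or more UMIs, in 155 mature cells (21.9%, 18.9 to 25.1%), whereas no OR led more than 7. The same share was 13.2% (7.00 to 21.9%) in the Calb2-led cluster and 2.42% (0.502 to 6.91%) in the Gap43-led cluster, and no cell of the earliest cluster was led by the transgene.

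**Figure D1:**
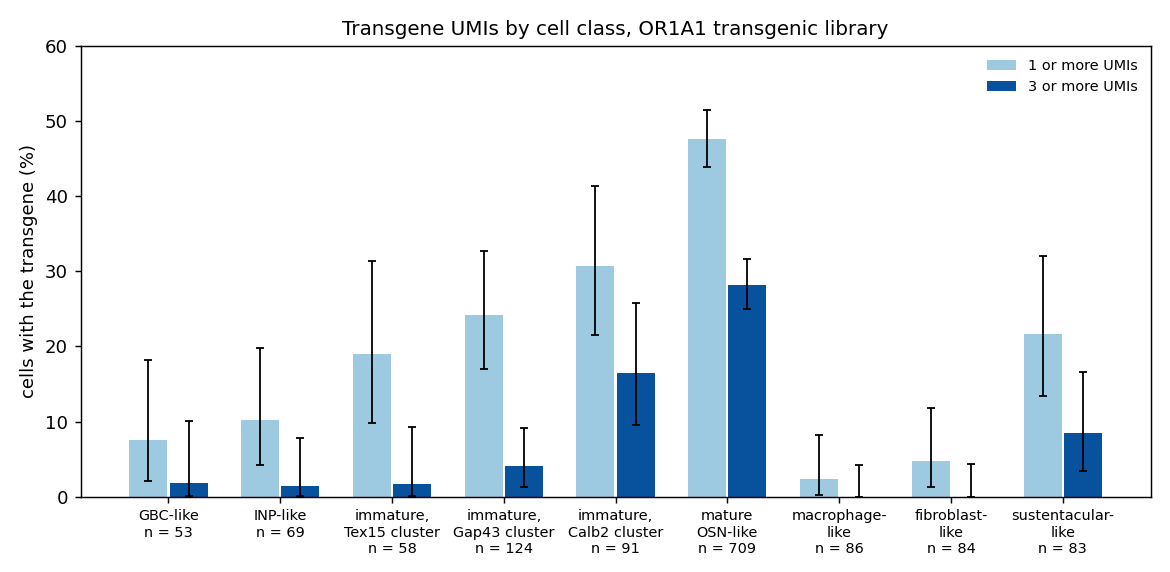
Share of cells of the transgenic library (percent, vertical axis) with at least 1 and with 3 or more transgene UMIs, by class or cluster of the neuronal lineage and in 3 non-neuronal classes; error bars are exact 95% binomial intervals (counting error only). At 3 or more UMIs the share was 4.03% in the Gap43-led immature cluster, 16.5% in the Calb2-led cluster, 28.2% in mature OSN-like cells and 0% in fibroblast-like cells.

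Other features are tied to the constructs by name. The second added feature, 10G4, was found in 9.03% of transgenic mature cells (7.02 to 11.4%) and 12.1% of wild-type mature cells (9.24 to 15.4%), close to the 8.86% and 12.0% of the non-neuronal classes, and its log2 ratio was −0.63 (−1.15 to −0.11) in mature cells and 0.19 (−1.0 to 2.14) in immature cells, the latter turning negative under 7 other settings. Olfr160 (Or8a1) had 0 UMIs in transgenic and 66 in wild-type mature cells, all in 1 wild-type cell. Mapt, the microtubule-associated protein tau, was at 7.83 CPM in transgenic and 9.92 CPM in wild-type mature cells (log2 ratio −0.35, −0.85 to 0.17) and at 131 and 148 CPM in immature cells (−0.19, −0.44 to 0.08), the latter 0.01 at a minimum of 2000 UMIs. mCherry was not analysed here.

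Most mature OSN-like cells in both libraries held a single endogenous OR, and the transgenic library had more cells with none. At 3 or more UMIs per OR, 66.3% of transgenic mature cells (62.7 to 69.8%) held exactly 1 OR, 27.2% (24.0 to 30.7%) held 0 and 6.49% (4.79 to 8.56%) held 2 or more. The wild-type shares were 89.7% (86.5 to 92.3%), 7.25% (5.04 to 10.0%) and 3.08% (1.69 to 5.11%). The leading OR gave a median of 99.2% and 99.4% of a mature cell's OR UMIs, in the 501 and 419 cells with 10 or more of these. Endogenous OR transcripts summed to 6037 CPM in transgenic and 10016 CPM in wild-type mature cells, and among the cells with an OR the leading OR had a median of 94 and 117 UMIs. With each cell thinned to 7900 UMIs, which left out 39 transgenic and 45 wild-type cells, the shares with 0, 1 and 2 or more ORs were 27.9%, 67.5% and 4.63% in the transgenic and 7.32%, 90.2% and 2.44% in the wild-type library. The number of cells with 2 or more ORs depended on the calling rule: it took in 22.0% of transgenic and 16.7% of wild-type mature cells when ORs were called above free RNA, and 51.6% and 57.4% at 1 UMI. Near-identical OR genes can share reads, and how the authors' counting divided them is not given in the sources used here.

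**Figure D2:**
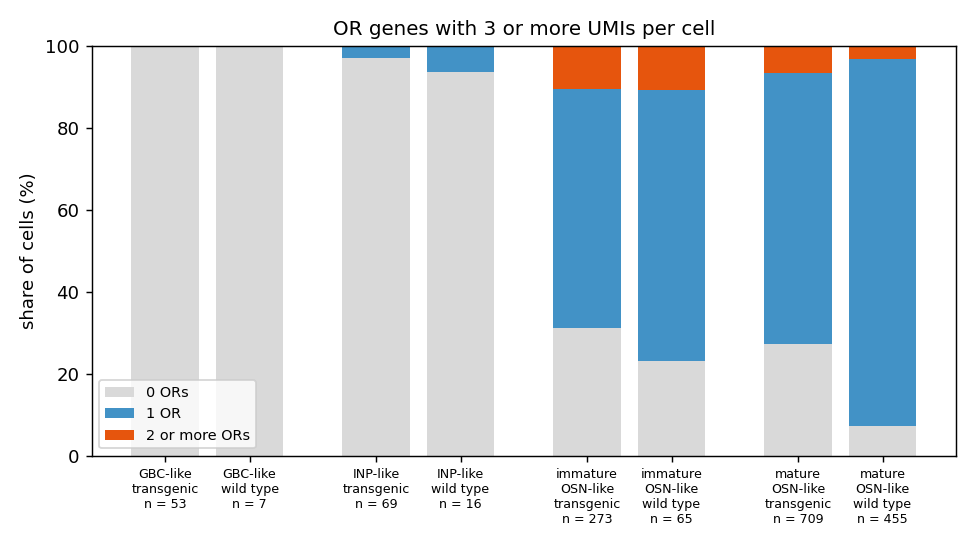
Stacked shares of cells (percent, vertical axis) with 0, 1 and 2 or more endogenous ORs at 3 or more UMIs, by class of the neuronal lineage and library, with no error bars and the number of cells under each bar. Cells with 0 ORs were 27.2% of the transgenic and 7.25% of the wild-type mature cells.

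Where 2 ORs were called in a cell they were often neighbours in the genome. Of 50 OR pairs in transgenic mature cells 31 lay within 200 kb of each other, as did 9 of 14 pairs in wild-type cells, by the gene order of the GRCm38 annotation. Cells with a pair farther apart were 2.40% (1.40 to 3.81%) of transgenic and 1.10% (0.358 to 2.55%) of wild-type mature cells. The most common pairs were Olfr55 with Olfr239 in 5 transgenic cells and Olfr1042 with Olfr1043 in 2 wild-type cells.

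Before maturity, ORs at 3 or more UMIs were close to absent in progenitors and common in immature OSN-like cells. No GBC-like cell (0 of 53 transgenic, 0 of 7 wild type) and no fibroblast-like cell (0 of 84, 0 of 44) held one. Other non-neuronal classes did, with 32.5% and 42.9% of sustentacular-like and 52.9% and 24.3% of erythroid-like cells. Over all non-neuronal cells the share was 8.49% transgenic (6.28 to 11.2%) and 6.55% wild type (4.43 to 9.27%), and the INP-like shares were not above it. In INP-like cells the share was 2.90% transgenic (0.353 to 10.1%) and 6.25% wild type (0.158 to 30.2%), and in immature OSN-like cells 68.9% (63.0 to 74.3%) and 76.9% (64.8 to 86.5%). Immature cells with 2 or more ORs were 10.6% (7.23 to 14.9%) and 10.8% (4.44 to 20.9%), and 5.30% and 6.45% after thinning to 7900 UMIs. The earliest immature cluster held many ORs at low counts: a mean of 10.1 ORs per transgenic cell and 21.7 per wild-type cell at 1 UMI (6.23 and 9.57 after thinning, 7 wild-type cells), of which the leading OR gave a median of 14.3% and 9.60% in the 31 and 6 cells with 10 or more OR UMIs. The mean number of ORs was 3.05 and 3.03 in the Gap43-led cluster, 1.91 and 2.05 in the Calb2-led cluster and 1.68 and 1.89 in mature cells. Shares of cells with any OR in GBC-like and INP-like cells reached 62.3% and 65.2% in the transgenic library at 1 UMI, and 15.1% and 21.7% when ORs were called above free RNA. No non-neuronal share was computed under these rules. At 1 UMI, transgenic GBC-like, INP-like and all non-neuronal cells alike had a median of 1 OR. After thinning their means were 0.302, 0.603 and 0.667 ORs, so the GBC-like and INP-like means were not above the non-neuronal one.

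Within the transgenic library, mature cells with many transgene UMIs mostly lacked an endogenous OR. Of the 371 cells with 0 transgene UMIs, 93.8% (90.8 to 96.0%) held an endogenous OR at 3 or more UMIs, against 49.7% (44.2 to 55.2%) of the 338 cells with at least 1. The share was lower at higher transgene counts, with 86.1% of 108 cells with 1 UMI and 83.3% of 30 cells with 2, then 16 of 32 cells with 3 to 4, 18.0% of 61 cells with 5 to 9 and 21.5% of 107 cells with 10 or more. Endogenous OR transcripts were 7934 CPM in cells without the transgene and 1586 CPM in the 168 cells with 5 or more transgene UMIs, while Omp was 4946 and 4745 CPM and the median depth 14372 and 13244 UMIs. Cells with both 5 or more transgene UMIs and an endogenous OR numbered 34, against 122 if both had been independent. Their leading OR had a median of 71.5 UMIs beside a median of 12 transgene UMIs, and 22 of the 34 had 50 or more UMIs of it. Mature cells with neither the transgene nor an OR were 3.24% (2.07 to 4.83%) with the transgene counted at 1 UMI, 6.06% (4.42 to 8.08%) at 3 UMIs and 8.32% (6.39 to 10.6%) at 5 UMIs, beside the 7.25% (5.04 to 10.0%) of wild-type mature cells without an OR. The share with an OR among transgene-positive cells depended on the minimum, and was 25% (19.2 to 31.6%) at 3 UMIs and 20.2% (14.4 to 27.1%) at 5 UMIs, both minima chosen after the data had been seen. Some non-neuronal cells also held 1 or 2 transgene UMIs, and whether free RNA gave such counts was not tested.

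**Figure D3:**
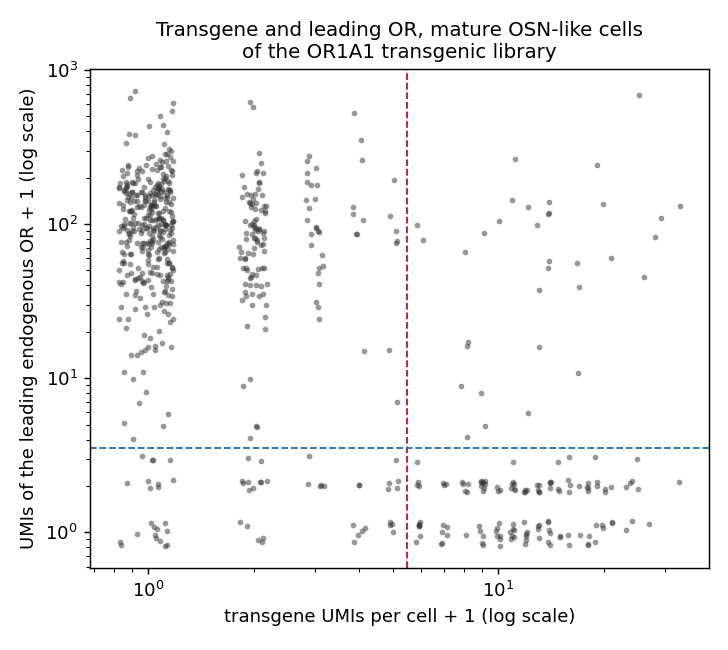
Each point is 1 of the 709 mature OSN-like cells of the transgenic library, with its transgene UMIs plus 1 (horizontal log axis) and the UMIs of its leading endogenous OR plus 1 (vertical log axis), moved slightly at random so that points stay visible; dashed lines mark 5 transgene UMIs and 3 OR UMIs. An OR at 3 or more UMIs was found in 93.8% of cells with 0 and 20.2% of cells with 5 or more transgene UMIs.

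The repertoire of endogenous ORs was wide in both libraries. In the transgenic library 328 ORs led at least 1 of 516 OR-expressing mature cells, and in the wild-type library 278 ORs led 422 cells, with 121 ORs leading in both. Drawing 422 OR-expressing transgenic cells gave 285.8 ± 4.08 leading ORs (SD over 100 draws), against 278 in the wild type. Drawing 455 mature cells, with or without an OR, gave 240.8 ± 5.67 against 278. The wild-type cells were taken whole in both. These SDs cover the random drawing only, and neither the sampling of cells from an animal nor a spread between animals. Olfr1507 led most transgenic cells (7), followed by Olfr1271, Olfr1361, Olfr1564 and Olfr455 (6 each). In the wild type Olfr77 led 7 cells, Olfr1321 led 6 and Olfr1226, Olfr1247 and Olfr969 led 5 each. Olfr1507 was the only OR to lead 10 or more cells in all, with 1.36% of transgenic (0.547 to 2.78%) and 0.948% of wild-type (0.259 to 2.41%) OR-expressing cells. Class I receptors, the fish-like group, led 8.85% of transgenic (6.51 to 11.7%) and 13.6% of wild-type (10.4 to 17.2%) cells whose leading OR had a known class, and the intervals overlapped. A first reading of the class, corrected after its values had been seen, gave 10.1% and 13.6%.

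In mature OSN-like cells, the medians of the lists tied to neuronal activity and to dissociation stress were above 0 (transgenic over wild type), and those of olfactory signalling, OR gene choice and the ventral and dorsal zones below 0, with most members under 1.5-fold. Of 6845 genes other than ORs with at least 20 CPM and 50 UMIs in a library, 52 were 2-fold or more higher and 93 were 2-fold or more lower in the transgenic library, with a median log2 ratio of −0.03. The activity-associated list had a median log2 ratio of 0.37, at percentile 99.95 of 10000 random lists matched on expression. Of its 8 measured genes 3 were over 1.5-fold higher and 0 lower: Pcp4l1 (1.25), Kirrel2 (1.01), an adhesion molecule of OSN axons, and S100a5 (0.81), a calcium-binding protein of OSNs that also leads 2 of the mature clusters, while Srxn1 (−0.18) and Kcnn2 (−0.11) went the other way. The dissociation and heat stress list stood at 0.40 (percentile 99.96), with 2 of 7 genes over 1.5-fold higher, the immediate early genes Junb (1.13) and Egr1 (0.78), Fos at 0.40 and Dusp1 at −0.19. Free RNA held Junb (504 against 333 CPM), Egr1 (183 against 118) and Fos (504 against 285) above their levels in the mature cells and also higher in the transgenic library. Dusp1 (174 against 135) was higher there too, and Hsp90aa1 (533 against 244) was below its level in the cells. The part of free RNA in these ratios was not tested. Signal transduction had a median of −0.19 (percentile 0.3) over 15 genes, of which the phosphodiesterase gene Pde4a (−0.65) alone passed 1.5-fold, with Ric8b at −0.47 and adenylyl cyclase 3 (Adcy3) at −0.35. OR gene choice and nuclear regulators stood at −0.20 (percentile 0.745) over 17 genes, with 2 over 1.5-fold lower, the histone methyltransferase gene Ehmt1 (−1.28) and the homeobox gene Emx2 (−0.75), and Ebf4 at −0.52. The ventral zone list was at −0.43 (percentile 0.42) over 5 genes, led by Nfia (−1.42), Nrp2 (−0.53) and Nfib (−0.43), and the dorsal zone list at −0.30 (percentile 1.83) over 4 genes, with Nqo1 at −0.75, Plxna1 at −0.47 and Acsm4 at 0.47.

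The remaining lists stood closer to random lists or had members that parted. Axon guidance genes had a median of −0.13 (percentile 6.08, mean −0.02) and went both ways: Tenm4 (1.60), Kirrel2 (1.01), Nrp1 (0.91) and Pcdh17 (0.89) were over 1.5-fold higher, and Efna5 (−1.68), Kirrel3 (−1.04) and Pcdh10 (−0.97) over 1.5-fold lower, among 15 measured. The list of OR feedback and unfolded protein response was at 0.08 (percentile 81.3) over 8 genes, with Hspa5, the chaperone BiP, at 0.72, Asns at 0.47 and Atf4 at 0.41. These 8 leave out the list's member Ddit3, which was higher in the transgenic library (218 against 134 CPM). The median and percentile hold only without it. Mitochondrial transcripts were at −0.07 (percentile 14.5) over 13, with mt-Atp8 (−1.15) and mt-Nd4l (−0.71) lower. Of 41 trace amine and other non-OR receptor genes only Car2 (0.38) and Gucy1b2 (−0.86) reached the minimum. Omp was level between libraries at −0.04 (−0.06 to −0.02), a sign that median-of-ratios scaling turned to 0.02, and Gap43 was higher, at 119 against 52.4 CPM (log2 1.18, 1.00 to 1.36). Free RNA held Gap43 at 202 against 81.0 CPM, above its level in the mature cells of both libraries, and its part in this ratio was not tested.

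**Figure D4:**
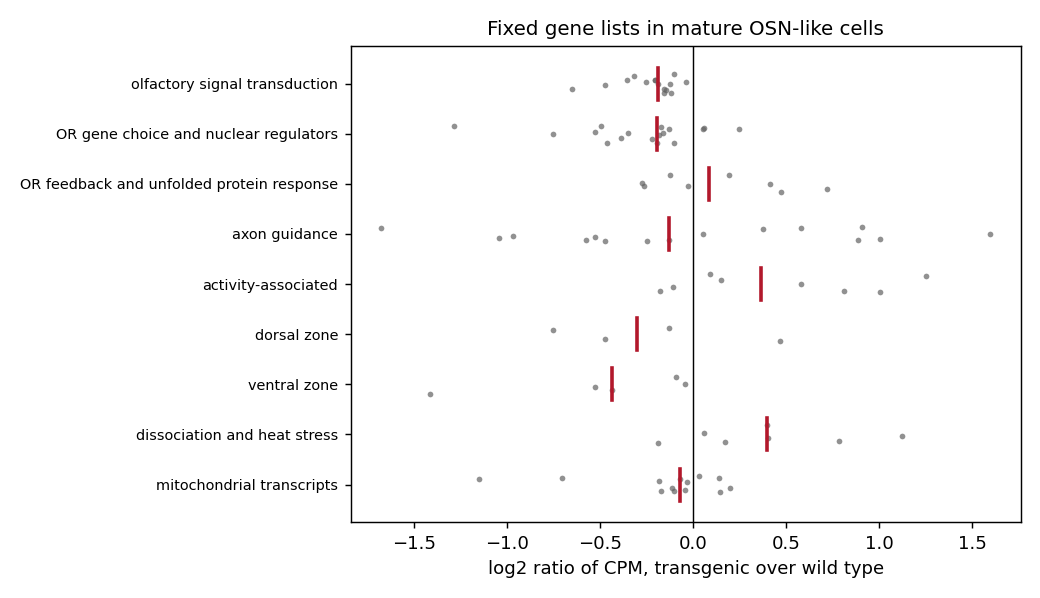
Log2 ratio of transgenic over wild-type CPM (horizontal axis) of the measured members of each fixed gene list in mature OSN-like cells, with points for single genes, red bars for list medians and no error bars. The median of the activity-associated list stood at 0.37 and that of the ventral zone list at −0.43.

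The clusters within the 2 classes took different shares of the libraries. The Tex15-led, Gap43-led and Calb2-led clusters gave 58, 124 and 91 of the 273 transgenic and 7, 37 and 21 of the 65 wild-type immature cells. Among mature cells, 1 of the 3 clusters held 230 of 709 transgenic and 95 of 455 wild-type cells, and another, led by Stoml3, held 62 and 69. With the transgenic clusters weighted as in the wild-type library, an alternative chosen after the results had been seen, the mature list medians were 0.32 (activity-associated), 0.31 (dissociation and heat stress), −0.15 (olfactory signal transduction), −0.21 (OR gene choice and nuclear regulators), −0.50 (ventral zone) and −0.27 (dorsal zone), with Adcy3 at −0.28 and Gap43 at 0.76. The immature medians were −0.34 for olfactory signal transduction and −0.47 for the ventral zone, with Omp at −0.10. By cluster, Adcy3 was at 49.0 (transgenic) against 109 CPM (wild type) and Omp at 246 against 450 CPM in the Gap43-led cells, and at 127 against 123 CPM and 2185 against 2089 CPM in the Calb2-led cells.

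Markers of other classes were measured in the same mature cells. Mature OSN markers were at −0.17 (percentile 1.26), immature OSN markers at 0.30 (percentile 98.9, 4 genes), INP markers at 0.69 (percentile 99.9, 3 genes) and respiratory ciliated markers at 0.22 (percentile 94.6, 3 genes). Of the 10 mature OSN markers only Umodl1 and Carns1 are not also in the olfactory signal transduction list. The medians of these lists thus rest largely on the same genes. Each of these immature OSN and INP genes was also higher in free RNA of the transgenic library. Gap43 stood there at 202 against 81.0 CPM, Sox11 at 272 against 85.3 and Insm1 at 56.9 against 11.3. Crmp1 (24.7 against 11.3 in free RNA) was lower in the mature cells (−0.85). How much of these ratios came from free RNA was not tested. The sustentacular genes Cyp2g1 (1.02) and Cyp2a5 (1.13) and the Bowman's gland gene Bpifb4 (1.32) were higher in the transgenic library, which also held the larger sustentacular-like share, and the neutrophil genes S100a8 (−1.65) and S100a9 (−2.41) were lower, as was the neutrophil-like share. Obp2b (−3.50) was lower and the haemoglobin genes Hba-a1 (1.47) and Hbb-bs (0.71) higher. The class shares went the other way: the Bowman's gland-like share was higher (1.15 against 0.716%) and the erythroid-like share lower in the transgenic library. An unnamed cluster led by lipocalin and odorant-binding protein genes, Obp2b among them, held 11 transgenic and 17 wild-type cells. Free RNA of the transgenic library held less Obp2b (228 against 1013 CPM) and more Hba-a1 (3520 against 1566) and Hbb-bs (6236 against 5733). It also held less S100a8 (300 against 4952 CPM) and more Cyp2a5 (1323 against 667) and Bpifb4 (717 against 293). Fabp7 stood at 0.53, Coch at −0.30, Gnao1 at −0.22, Pcna at −0.12 and Ezh2 at 0.10. Coch (534 against 305 CPM), Gnao1 and Pcna were higher in free RNA of the transgenic library but lower in its mature cells. Whether free RNA gave the ratios of these markers was not tested. No marker of the horizontal basal, tuft, macrophage, B, T or NK, mast, endothelial, pericyte or fibroblast classes reached the minimum.

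The genes with the largest single ratios in mature cells included a long non-coding RNA, a pseudogene and predicted genes beside protein-coding genes, and some differed in other cell classes too. Miat, a long non-coding RNA, was at 28.0 against 0.513 CPM (3 wild-type UMIs, log2 5.36, 4.21 to 8.05). Pop4, a subunit of RNase P, followed at 40.0 against 8.38 CPM (2.23, 1.82 to 2.71), with ratios of 1.38 in sustentacular-like, 1.09 in macrophage- or monocyte-like (38 UMIs), 0.89 in endothelial-like and −0.43 in fibroblast-like cells (31 UMIs). Also higher were C230038L03Rik (1.90, with 138 of its 244 transgenic UMIs from the 134 cells with 5 or more transgene UMIs and no OR), the calcium-binding S100a3 (1.90), the synaptic scaffold gene Dlg2 (1.89, 626 against 169 CPM, a leading gene of a mature cluster), 6330403K07Rik (1.87), 1110018N20Rik (1.85), the prohormone convertase gene Pcsk2 (1.84), Ly6h (1.80) and S100a6 (1.77), of whose transgenic UMIs 18.5% came from 1 cell. Rps18-ps6, a ribosomal protein pseudogene whose reads can be shared with its parent gene, was at least 182-fold lower, at 0 UMIs against 54.1 CPM, and, also with 0 transgenic UMIs, at least 125-fold lower in sustentacular-like, 52.6-fold in macrophage- or monocyte-like, 38.8-fold in fibroblast-like and 57.5-fold in endothelial-like cells. Gm31557 had 1 transgenic UMI (−7.29, −13.60 to −5.79), with at most 1 UMI in each of these other classes. Gm35082 also had 1 (−8.30, −14.60 to −6.81). Pttg1, the separase inhibitor securin, had 2 (−6.94, −10.57 to −5.64), as did Tmsb15b1 (−6.13, −9.77 to −4.82). These genes were also lower in the 4 other classes named above. Gm35082 stood at −6.54 in sustentacular-like (23 UMIs) and −5.61 in endothelial-like cells (45 UMIs). Pttg1 stood there at −2.32 (46 UMIs) and −1.16 (57 UMIs), and Tmsb15b1 had at most 11 UMIs in any of the 4. Fam183b was at 1.98 against 57.0 CPM (−4.78, −5.57 to −4.19) and Gldc, the glycine decarboxylase of mitochondria, at 3.87 against 58.5 CPM (−3.89, −4.44 to −3.44). Other ratios rested on very few cells: 4930516K23Rik (at least 110-fold lower) on 1 wild-type cell for 99.5% of its UMIs, Esp22 (at least 73.0-fold lower) on 1 wild-type cell, and Gm10310 (−6.85, −13.16 to −5.34) on 4 wild-type cells and 1 transgenic UMI. When the 5% of cells with the highest doublet scores were left out, no ratio remained for 4930516K23Rik (0 transgenic UMIs and 1 wild-type UMI) or Esp22 (0 UMIs in both libraries).

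In immature OSN-like cells, the medians of the signal transduction and ventral zone lists were below 0, and the axon guidance genes again went both ways. Among 6874 genes measured, 48 were 2-fold or more higher and 36 were 2-fold or more lower, with a median log2 ratio of −0.01. Signal transduction genes stood at −0.40, below all 10000 random lists, with 2 of 14 over 1.5-fold lower, the channel genes Cngb1 (−0.96) and Ano2 (−0.60), and Pde4a at −0.58. The ventral zone list was at −0.40 (percentile 0.085), with Nrp2 (−0.78) and Nfia (−0.74) over 1.5-fold lower among 5, and OR gene choice regulators were at −0.15 (percentile 1.09), with Ehmt1 (−1.04) alone past 1.5-fold among 16. Axon guidance genes were at 0.11 (percentile 91.5) over 15, with Nrp1 (0.91), Kirrel2 (0.90), Pcdh10 (0.75) and Tenm4 (0.68) over 1.5-fold higher and Nrp2 (−0.78), Efna5 (−0.69) and Kirrel3 (−0.62) over 1.5-fold lower. The activity-associated list was at 0.12 (percentile 88.5) over 7, with S100a5 (1.44) and Kirrel2 (0.90) higher and Cidea (−0.70) lower. Free RNA held S100a5 at 7062 (transgenic) against 3645.5 CPM (wild type), above its level in the immature cells (1115 against 411 CPM). Kirrel2 was also higher in transgenic free RNA (205 against 90.1 CPM), as was Cidea (29.9 against 18.6 CPM), which was lower in the cells. How far free RNA shaped these ratios was not tested. Stress genes stood at 0.13 (percentile 92.3) over 8 with Atf3 (0.89) higher, feedback and unfolded protein response genes at −0.04 (percentile 30.0) over 9 with Hspa5 (0.69) higher, Rtp1 at −0.50 and Trib3 at 0.38, dorsal zone genes at −0.02 (percentile 50.1) over 4 and mitochondrial transcripts at −0.05 (percentile 13.3) over 13 with mt-Atp8 (−1.03) and mt-Nd4l (−0.62) lower. The 9 feedback genes again leave out Ddit3. It was higher in the transgenic Gap43-led (417 against 212 CPM) and Calb2-led cells (562 against 267 CPM) and lower in the Tex15-led cells (20.4 against 32.3 CPM). Of the non-OR receptors, Car2 and Taar6 reached the minimum.

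Gap43 was at 0.13 (0.06 to 0.20) and Omp at −0.18 (−0.27 to −0.08) in these cells. Mature OSN markers stood at −0.35 (percentile 0.04), immature OSN markers at −0.00 (percentile 40.0), INP markers at −0.10 (percentile 16.4), GBC markers at 0.35 (percentile 98.3, 3 genes) and respiratory ciliated markers at −0.10 (percentile 40.5, 3 genes). The mature OSN markers again share most of their genes with the olfactory signal transduction list. Sustentacular markers, at 1.59 (percentile 99.9), were all higher: Cyp2g1 (1.74), Cyp2a5 (1.59) and Cbr2 (1.39). Free RNA of the transgenic library also held more Cyp2g1 (834 against 507 CPM) and Cyp2a5 (1323 against 667 CPM), and its part in these ratios was not tested. Hba-a1 (2.25), Hbb-bs (0.64) and Fabp7 (0.70) were higher, and Coch (−0.90) and Gnao1 (−0.34) lower. By the rule of size, the genes named as higher were Vmn1r200 (at least 15.9-fold, 99.5% of its UMIs from 1 cell), Gm48860 (at least 9.32-fold, 4 cells), the trace amine receptor gene Taar6 (at least 8.82-fold, 3 cells), Gm3896 (at least 7.29-fold, 32 cells) and Miat (log2 4.05, 2.53 to 10.35, with 1 wild-type UMI). Those named as lower were Ovch2 (at least 170-fold, 1 wild-type cell), Rps18-ps6 (at least 144-fold), 9230009I02Rik (−6.88, −13.19 to −5.32, 1 wild-type cell and 1 transgenic UMI), Car2 (−4.05, −4.55 to −3.62, 85.5% of its wild-type UMIs from 1 cell) and Resp18 (−4.02, −5.05 to −3.24, 95.1% from 1 wild-type cell). Ovch2 and Gm48860 were also leading genes of the Calb2-led cluster. The class took in fewer transgenic cells (213 to 255, against 273) under each of the 7 other ways of keeping or clustering cells. Over these, Omp ran from −0.53 to −0.93, S100a5 went down to 0.31, Kirrel2 to 0.07, Atf3 to 0.14 and Miat to 2.31, and Cidea reached −1.43. Gm48860 was at least 2.02-fold to 2.34-fold and Gm3896 at least 1.86-fold to 4.03-fold higher, and Car2 ran from −3.32 to −7.35. Resp18 ran from −5.84 to −7.51, with no ratio at a minimum of 500 UMIs (2 transgenic and 3 wild-type UMIs). Ovch2 had 0 UMIs in both libraries at that minimum and without the highest doublet scores, and was at least 154-fold to 162-fold lower in the others. Nqo1 (−0.41), Trib3 and the medians of the dorsal zone, feedback, axon guidance and activity-associated lists changed sign in at least 1.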

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

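The removal of the cells with the highest doublet scores, the transgene minima of 3 and 5 UMIs for endogenous ORs, the counting of pseudogenes as ORs and the weighting of clusters as in the wild type were chosen after the results had been seen, and the other alternatives were planned. Of 359 shares and counts recomputed, 276 stayed within the main 95% interval or within 1.5 times the main count and 83 moved. Of 1387 values for single genes and list medians, 1215 stayed, 143 moved in the same direction and 29 changed sign. A single gene stayed if it lay in its main interval, and a list median if it lay within 1.5-fold of its main value. Each main median of the fixed lists was itself under 1.5-fold, so for lists this count says little beyond the sign. No ratio was given where neither library held more than 3 UMIs, which was so for Ovch2 and Resp18 in immature cells at a minimum of 500 UMIs and for Ovch2 in immature and 4930516K23Rik and Esp22 in mature cells without the highest doublet scores. Under each alternative that gave both values, the share of mature cells without an OR was higher in the transgenic (13.1 to 29.2%) than in the wild-type library (2.86 to 8.17%), and transgene-negative mature cells held an OR more often (87.5 to 96.5%) than transgene-positive ones (20.2 to 76.3%). The causes of the moves below were not tested, except where a minimum counts fewer UMIs or cells by construction. No paired analysis was possible because each group held 1 library, both numbered replicate 1. Few cells limit the wild-type GBC-like (7 cells), INP-like (16) and early immature (7) values, whose median depths of 33996, 18853.5 and 18493 UMIs were above the 12547 of wild-type mature cells.

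With a minimum of 500 UMIs, transgene-positive shares were 18.0% of immature and 42.7% of mature cells, immature cells with any OR 51.0% (transgenic) and 64.7% (wild type), and transgene-negative cells with an OR 87.5%. GBC-like shares were 1.34% and 4.54%, the transgenic INP-like share 2.85%, immature shares 11% and 3.67%, and the wild-type mature share 37.5%. In immature cells the log2 ratio of 10G4 was −0.14, of Nqo1 0.11, of Trib3 −0.016 and the axon guidance median −0.13. At 2000 UMIs, 18.2% of transgenic GBC-like cells had an OR, GBC-like shares were 0.547% and 3.50%, the transgenic immature share 12.0% and the wild-type mature share 37.0%. At both minima the GBC-like name covered a different set of cells than in the main setting. There, 60 genes were lower in immature cells, where 10G4 was at −0.33, Mapt at 0.011 and the feedback list at 0.044.

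Without doublet removal the transgenic immature and mature shares were 12.5% and 43.8%, and in immature cells 10G4 was at −0.30, Nqo1 at 1.21, the OR feedback and unfolded protein response list at 0.027 and the dorsal zone list at 0.29. With the highest doublet scores removed, these shares were 12.8% and 44.4%, and in immature cells 10G4 was at −0.21, Nqo1 at 0.91, Trib3 at −0.19 and the dorsal zone list at 0.34. With mitochondrial shares up to 20%, the transgenic INP-like share was 3.08%, immature shares were 9.62% and 3.82% and mature shares 35.7% and 33.9%. There, 58 genes were lower in immature cells, where 10G4 was at −0.29, Nqo1 at 0.000619, Trib3 at −0.12, the activity-associated list at −0.029 and the dorsal zone list at 0.092.

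At resolution 0.5 no cluster was named GBC-like, so its share was 0% in both libraries and its OR and transgene shares had no value; the transgenic INP-like, immature and mature shares were 5.22%, 12.7% and 44.3%, and 61 genes were lower in immature cells, where 10G4 was at −0.32, Nqo1 at 0.81 and the dorsal zone list at 0.21. At resolution 2 the transgenic GBC-like, INP-like and immature shares were 1.89%, 5.10% and 12.8%, and in immature cells 10G4 was at −0.23, Nqo1 at 0.83, the feedback list at 0.017 and the dorsal zone list at 0.15. Median-of-ratios scaling turned Omp in mature cells to 0.017. With clusters weighted as in the wild type, the feedback list in immature cells was at 0.024. With no minimum beyond 10 UMIs, 445 genes were higher and 643 lower in mature cells and 394 and 646 in immature cells.

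Counting an OR at 1 UMI gave 13.1%, 35.3% and 51.6% of transgenic mature cells with 0, 1 and 2 or more ORs, and 2.86%, 39.8% and 57.4% of wild-type ones. Any OR was then found in 62.3% and 71.4% of GBC-like, 65.2% and 62.5% of INP-like and 95.2% and 93.8% of immature cells (transgenic and wild type), and in 76.3% of transgene-positive and 96.5% of transgene-negative mature cells. At 2 UMIs, 10.0% of transgenic and 7.69% of wild-type mature cells had 2 or more ORs, 85.5% of wild-type ones had 1, and 79.1% of transgenic immature cells had any. At 5 UMIs 0% of wild-type INP-like cells had an OR. Calling ORs above free RNA gave 20.9%, 57.1% and 22.0% of transgenic mature cells with 0, 1 and 2 or more, and 78.0% and 16.7% of wild-type ones with 1 and with 2 or more. Any OR was then found in 15.1% of transgenic GBC-like cells, 21.7% and 31.2% of INP-like cells, 84.2% and 89.2% of immature cells and 61.2% of transgene-positive mature cells. With OR pseudogenes counted, 4.62% of wild-type mature cells had 0 ORs. Shares in non-neuronal cells were not recomputed under these rules, so the GBC-like and INP-like shares have no background beside them here.

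The transgene at 2 UMIs was found in 1.45% of INP-like, 11% of immature and 32.4% of mature cells, and at 3 UMIs in 1.89% of GBC-like, 1.45% of INP-like, 7.69% of immature and 28.2% of mature cells. With cells thinned to one depth, in a second random thinning, it was found in 16.3% of immature and 37.8% of mature cells, and 0% of wild-type INP-like cells had an OR. Transgene-positive cells at 3 and 5 UMIs held an OR in 25% and 20.2%.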

Other observations

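The gene comparison between cells with and without high transgene counts, the one of cells without the transgene, the genes named and list values within both, the OR genes named for the earliest immature cluster, the genes followed along the lineage and the tests of free RNA in cells with both receptors and of the lower share in the Gap43-led cluster were chosen after the results had been seen; the tests of depth, damaged cells, other chemoreceptors and paired neurons were written before their results. Within the transgenic library, 134 mature cells with 5 or more transgene UMIs and no endogenous OR were set against 348 mature cells with an OR and 0 transgene UMIs, so that strain, age and library were shared. Of 6466 genes, the 10 with the largest ratios upward were C230038L03Rik (3.53), Tenm4, a teneurin of synaptic matching (335 against 45.0 CPM, log2 2.89, 2.67 to 3.12, found in 126 of 134 against 103 of 348 cells), Edem1 (2.27), Trib3 (2.25), Snd1 (2.24), Adamdec1 (2.15), Tmbim6 (2.02, 6336 against 1560 CPM), Dgkk (2.01), Actr3b (1.91) and Erlin1 (1.86). The 10 downward were Avp (0 UMIs, at least 104-fold, with 90.5% of the other cells' UMIs from 1 cell), Fxyd2 (−5.39), Cd55 (−4.81), Dio2 (−4.51, 2 UMIs), Pcdh8 (−4.12, 2 UMIs), Scg2 (−3.65, 3 UMIs), Il1b (−3.34, 93.2% from 1 cell), Rasl11a (−3.27), Rprm (−3.23) and Mboat1 (−3.16). Avp and Fxyd2 were also the foremost leading genes of 1 mature cluster. There 24.8% of transgenic cells (19.3 to 30.9%) held 3 or more transgene UMIs, against 29.5% (25.2 to 34.1%) and 32.3% (20.9 to 45.3%) in the other mature clusters. The 2 sets of cells were not matched by cluster. Among the other members of the fixed lists, Tenm2 (1.61) was the highest and Emx2 (−1.94), Nqo1 (−1.46) and Pcdh10 (−1.15) were the lowest. Ventral zone genes had a median of −1.06 (percentile 0.005), with Nfia (−1.10), Nfix (−1.06), Ncam2 (−1.07) and Nfib (−0.60) lower and Nrp2 at 0.10. The dorsal zone list stood at 0.05 (percentile 66.3), with Acsm4 (0.89) and Robo2 (0.60) higher and Nqo1 lower. Signal transduction was at 0.13 (percentile 99.4), axon guidance at 0.19 (99.2), the feedback and unfolded protein response list at 0.17 (96.5, with Trib3 far above Hspa5 at 0.17, Atf4 at 0.18, Rtp2 at −0.06 and Asns at −0.24), the activity-associated list at 0.11 (88.9), OR gene choice at 0.02 (64.0) and stress genes at −0.32 (0.37). The feedback value leaves out Ddit3 here as well.

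With the transgene-positive cells left out, the 348 transgenic cells with an OR and 0 transgene UMIs were set against the 422 wild-type mature cells with an OR. Tenm4 stood at 0.42 (0.13 to 0.71, 45.0 against 33.7 CPM) and C230038L03Rik at 0.27 (−0.47 to 1.04, 34 and 30 UMIs), against 1.60 and 1.90 over all mature cells. Among the other genes Miat stood at 5.05, Pop4 at 2.33, Dlg2 at 2.20, S100a3 at 2.04, Kirrel2 at 0.97, Ehmt1 at −1.29, Gldc at −3.34 and Fam183b at −5.77, and the transgenic cells held 0 UMIs of Rps18-ps6, Gm35082, Gm31557 and Tmsb15b1. No ratio was left for 4930516K23Rik (0 and 1 UMIs) and Gm10310 (0 in both). List medians were 0.46 for the activity-associated list, 0.35 for dissociation and heat stress, −0.31 for olfactory signal transduction, −0.27 for OR gene choice and nuclear regulators, −0.28 for axon guidance, −0.33 for the ventral zone and −0.32 for the dorsal zone.

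Some mature cells without an OR held an OR pseudogene feature or a trace amine receptor. Of 33 wild-type mature cells without an OR, 12 had 3 or more UMIs of an OR pseudogene and 2 of a trace amine receptor (14 in all, 42.4%, 25.5 to 60.8%). Of 59 transgenic mature cells with under 5 transgene UMIs and no OR, 11 and 6 did (28.8%, 17.8 to 42.1%). In the earliest immature cluster the most widespread ORs among both libraries' cells were Olfr482 (8 of 58 transgenic and 2 of 7 wild-type cells), Olfr24 (5 and 5) and Olfr655 (7 and 1), while Olfr959 and Olfr223, in 6 transgenic cells each, were in more of these than Olfr24. These are detections at 1 UMI, of which free RNA can give some: Olfr482 was also found in 6.46% of the 542 non-neuronal transgenic cells, Olfr24 in 1.66%, Olfr655 in 1.11%, Olfr959 in 0.554% and Olfr223 in 0.185%. Olfr482 and Olfr223 led 0 mature cells. The stress gene Ddit3, the member that the feedback list values leave out, was at 20.4 (transgenic) and 32.3 CPM (wild type) in that cluster, 417 and 212 CPM in the Gap43-led cluster, 562 and 267 CPM in the Calb2-led cluster and 218 and 134 CPM in mature cells. Lhx2 went from 3664 and 3374 CPM in INP-like cells to 650 and 625 CPM in mature cells.

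A first pattern is that mature cells with 5 or more transgene UMIs mostly lacked an endogenous OR. Lower depth is argued against, because after thinning to one depth the share without an OR still differed by 72.9 percentage points (80.5% against 7.58%). Omp stood at 0.959 times its level in cells without the transgene, and the mitochondrial share at 1.07 times. This comparison cannot decide on damage or another cell type. All cells in it had passed the mitochondrial filter and lay in clusters named by markers that include Omp. Uncounted chemoreceptors or OR pseudogenes are argued against, because 2.24% (0.464 to 6.40%) of cells with 5 or more transgene UMIs and no OR held one. A candidate explanation is that expression of the transgene stands in for the choice of an endogenous OR. This hypothesis was drawn from the same library, and none of these tests addressed it directly. Whether it holds in other animals was not tested.

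A second pattern is the 34 mature cells with both 5 or more transgene UMIs and an endogenous OR. Droplets with 2 neurons are argued against as the main source, because the median UMI count of these cells was 1.10 times that of cells with the transgene alone (1.05 to 1.18 when cells were resampled, 14328 against 13034 UMIs). Free transgene RNA is argued against as the whole source, because 6.59% of the 516 OR-expressing mature cells (4.61 to 9.09%) held 5 or more transgene UMIs, against 2.40% (1.28 to 4.07%) of the 542 cells of all non-neuronal classes. Of the 13 such non-neuronal cells, 7 were sustentacular-like and 4 erythroid-like. In these classes the cells with 3 or more transgene UMIs carried Omp at 1759 and 5771 CPM, so the 2.40% may not be free RNA alone. No fibroblast-like, macrophage- or monocyte-like or horizontal basal cell-like cell held more than 1 transgene UMI, but 1 endothelial-like cell held 5 or more. How that endothelial-like cell came to hold its count was not tested. Free RNA held 98 transgene UMIs among 2143260. The 34 cells had a median of 12 transgene UMIs among a median of 14328 UMIs. Free RNA of that makeup, even if it filled a droplet, is thus argued against as the source of 5 or more transgene UMIs in these 34 cells. These cells may be neurons that express both receptors, and they held 32 different leading ORs. Smaller subsets, such as the 5 cells whose leading OR had under 10 UMIs, were not tested apart.

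The last pattern is that cells with 3 or more transgene UMIs were rarer in the Gap43-led immature cluster (4.03%, 1.32 to 9.16%) than in mature cells (28.2%). Lower depth is argued against, because the median UMI count of the cluster was 1.15 times that of mature cells (1.08 to 1.19 when cells were resampled, 16306.5 against 14171 UMIs). A general scarcity of receptor transcripts is argued against as the whole source, since mature transgene counts had to be lowered 5.35-fold to bring their share to 9.16%, whereas the leading OR's median differed by 1.84-fold (1.31 to 2.20) among cells with an OR, and by 2.35-fold (1.85 to 3.23) between mature cells with 0 transgene UMIs and all cells of the cluster. Lowering each mature count by the first of these factors left 23.1% of mature cells at 3 or more. No biological explanation was tested, and a difference between the stages in how many cells express the transgene stays open.

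The differences between the 2 libraries in class shares, and those in gene levels that were also found among cells without the transgene, have no such tests. Strain background, age and genotype differ together in the design, and which of them underlies the ratio of a gene such as Rps18-ps6, which was lower in other classes as well, was not tested.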
